A study of Rattus norvegicus with 45 samples.

How the data were processed

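Total RNA was measured in 2 skeletal muscles of female Sprague Dawley rats, the gastrocnemius and the soleus, on 45 single-channel Affymetrix rat arrays, of which 30 were gastrocnemius and 15 soleus. Animals received vehicle (methylcellulose solution) or cerivastatin, a cholesterol-lowering drug of the statin class, for 14 days, with or without treadmill exercise. Per the labels' protocols, the RNA was extracted with a silica column kit, and about 4 µg from gastrocnemius or 3 µg from soleus was converted to biotinylated cRNA. Input RNA and muscle can therefore not be told apart in the comparison of the muscles, and no array dates were used here. Soleus samples whose title does not say that the animal ran were taken as unexercised. The labels name the replicates as biological, so that p-values measure the spread between animals.

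The deposited values are linear intensity values, 1 per probe set and array, that the authors made with MAS5, per the submitters' processing notes; its version and scaling target are not given in the sources used here. As a check on the scaling, the mean of each array after trimming 2% at either end lay between 600.2 and 600.31, while array medians ranged from 134.7 to 175.9 and maxima from 47263 to 110220. Every array was therefore used as the authors scaled it. The file held 31099 probe sets, and the 57 control probe sets were left out, leaving 31042. All value columns matched a sample. No pair of arrays held identical values, and the highest correlation between any 2 arrays was 0.97. Array data have no read depth, so their number limits the precision. A gene below the array's background is measured poorly, and the offset below makes its fold change smaller than the true one.

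Gene symbols came from the platform annotation. Of the 31042 probe sets, 20826 had 1 symbol, 436 had several and 9780 had none in that table, and no gene was named from a probe set with several. By gene identifier, 20764 matched the RefSeq gene table, and 0 of these had another symbol there. A gene was represented by its tested probe set with the highest mean over all 45 arrays, with the mean over all its probe sets as an alternative. Genome positions were not used here. Of the genes to be named in every comparison 3, and of the gene lists 1, are not reported here.

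Values were analysed as log2(value + 12.4), where the offset is the 10th percentile of all deposited values. Fold changes are on this scale. Probe sets with a mean at or above the 30th percentile (6.03 on this scale) were tested, which left 21729, of which 16235 had 1 symbol and stood for 11684 genes. Group means were fitted with limma (version 3.58.1, R version 4.3.3) using lmFit, contrasts.fit and eBayes with a mean-dependent prior variance. Comparisons within gastrocnemius used its 30 arrays, those within soleus its 15, and comparisons between muscles all 45, because groups of 3 or 4 arrays share 1 estimate of the spread in this way. P-values were adjusted by the Benjamini-Hochberg method within each of 19 comparisons, with a threshold of 0.05. An adjusted p in the text is limma's, Benjamini-Hochberg adjusted, unless a gene list test is named, and ± after a log2 fold change is its SE. The comparisons were each dose against vehicle, exercise against none in vehicle animals, the interaction of exercise with each dose, soleus against gastrocnemius in unexercised vehicle animals, the interaction of muscle with the high dose, and a linear trend over dose in gastrocnemius. The numbers that replicates carry in the labels were not used to pair animals.

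There were 33 gene lists with 961 symbols, of which 754 were tested. Only these tested members are called measured below. The filter uses the mean over all arrays, treated ones included, so it can keep a gene because the drug raised it. It kept 32 of 37 cell-cycle, 5 of 15 neutrophil and 15 of 24 lymphocyte list genes with a named probe set. They cover cholesterol and fatty acid synthesis, muscle atrophy, proteasome, lysosome and autophagy, myogenic regeneration and denervation, and stress responses (heat shock, oxidative stress, unfolded protein, p53 and apoptosis, immediate early genes). Others cover energy metabolism (oxidative phosphorylation, TCA cycle, fatty acid oxidation, glycolysis), calcium handling, fast and slow fibres, cell cycle, ribosomal proteins and extracellular matrix. Marker lists cover macrophages, lymphocytes, neutrophils, complement and interferon, adipocytes, endothelium, smooth muscle, Schwann cells, erythroid cells, mast cells and satellite cells. Each list was tested with camera, with a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. Adjustment was over the 33 lists within a comparison. Counts of list members are also given after adjustment over the list alone.

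Named genes followed a rule. It took the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose arrays did not overlap between the groups, except that interactions need only the threshold. It added the 3 largest changes past the threshold in every list, and a fixed set named whatever its values (Insig1, Rhob, Fbxo32, Trim63, Myog, Cdkn1a, Ankrd1, Pvalb, Myh7 and Myh4, besides the 3 not reported). The groups, tests, lists, naming rule and all alternatives except 2 were chosen before the data were examined. The alternatives were plain log2, an offset at the 25th percentile (45.3), quantile normalization, median centring, no filter, a filter at the 50th percentile, a prior variance without trend, a fit on only the groups compared, the replicate number as a block, dose rank in place of dose, and leaving out each array in turn. The 2 added after seeing the data leave out the 3 arrays with the lowest 5' to 3' signal ratio of the actin and Gapdh control probe sets, or add a score of slow-fibre genes as a covariate.

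The procedure was tested on simulated data over 21729 probe sets with 100 changed at each size. For the high dose in exercised gastrocnemius it recovered 33% of changes of 1 log2 unit and 64% of changes of 2 units, and for unexercised gastrocnemius 25% and 71%. For the high dose in exercised soleus these shares were 39% and 75%, and for soleus against gastrocnemius 39% and 81%. The noise was drawn independently for each probe set, whereas real arrays can deviate jointly. Far fewer probe sets were changed than the 9424 called for the real high dose in exercised gastrocnemius, which alters the adjusted threshold. The shares therefore check the procedure and do not give the sensitivity of the real comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.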

Results

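The arrays measured RNA abundance in the gastrocnemius, a mixed muscle with mostly fast fibres, and the soleus, a mostly slow muscle, of rats given cerivastatin for 14 days. Gastrocnemius was sampled at 0 (vehicle), 0.1, 0.5 and 1.0 mg/kg/day and soleus at 0 and 1.0 mg/kg/day, each with and without treadmill running at 20 m/min for 20 min on 5 days of the week. Of the 12 groups, 9 held 4 arrays and 3 groups held 3 arrays, namely unexercised gastrocnemius at 1.0 mg/kg/day, exercised gastrocnemius at 0.5 mg/kg/day and unexercised soleus at 1.0 mg/kg/day. The study set out to find what the drug does to muscle RNA, what exercise adds to it, and why muscles of different fibre type differ in sensitivity. The 5' to 3' signal ratio, a sign of RNA integrity, ranged from 0.116 to 0.707 for actin and from 0.475 to 0.888 for Gapdh.

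At 1.0 mg/kg/day, the gastrocnemius of exercised rats gained transcripts of macrophages, dividing cells, matrix and cholesterol synthesis, and lost transcripts of fast fibres, mitochondria, glycolysis and calcium handling. The largest rise was in Spp1 (osteopontin, a secreted matrix protein made by macrophages in injured tissue), by 7.08 ± 0.84 on the log2 scale, from a mean signal of 147.8 to 23600 (n = 4 in each group; limma, BH adjusted p = 5.05e-06). The monocyte-attracting chemokines Ccl2 and Ccl7 rose by 7.04 ± 0.93 and 6.75 ± 0.87. Rises of 5.43 to 6.29 were measured for Fcgr2b (an Fc receptor of myeloid cells), Gpnmb, Timp1 (a metalloproteinase inhibitor), Kcnn4 (a potassium channel) and Clec4a3. The largest fall was in Mss51, a muscle gene, at -6.31 ± 1.14 (mean signal 240.3 against 17840; limma, BH adjusted p = 0.000118). Tmem52, Ky, C8h3orf18, Fbp2 (muscle fructose bisphosphatase), LOC102552344, Ldb3 (a Z-disc protein) and Tmem233 fell by 5.01 to 4.43. For these 16 genes, all 4 treated arrays lay beyond all 4 vehicle arrays.

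Immune and proliferation genes rose together. All 33 measured macrophage and myeloid genes rose (33 adjusted over the list alone), with a median of 4.21. All 32 measured cell-cycle genes rose (32 adjusted over the list alone; median 2.49), among them Mki67 by 5.24 ± 0.81, Cks2 by 4.79 ± 0.96 and Prc1, a cytokinesis gene, by 4.71 ± 0.63. The complement and interferon list had 20 of 25 members higher (23 adjusted over the list alone), including the antigen peptide transporter Tap1 at 3.37 ± 0.57, C3 at 3.25 ± 0.69 and the immunoproteasome gene Psmb9 at 2.92 ± 0.38. Of 5 neutrophil genes 4 rose (5 adjusted over the list alone), with S100a9 at 5.34 ± 0.89 and S100a8 at 4.27 ± 0.97. Of 15 lymphocyte and antigen presentation genes 7 rose (9 higher and 1 lower adjusted over the list alone). Those with the largest change were RT1-DMa, Cd8a and RT1-DMb. Matrix genes rose in 34 of 44 cases and fell in 1 (the same numbers adjusted over the list alone), with Lum at 3.58 ± 0.54 and Fbln1 at 3.57 ± 0.78. Camera adjusted p was 9.64e-19 for the macrophage list, 3.28e-12 for cell cycle, 6.35e-07 for complement and interferon, 0.0118 for neutrophils, 0.0388 for lymphocytes and 2.37e-07 for matrix. None of these held with an estimated correlation (adjusted p = 0.417 with an estimated correlation for macrophages, cell cycle, complement and neutrophils, and adjusted p = 0.425 with an estimated correlation for lymphocytes and matrix). By fry, which tests movement in one direction only, adjusted p was 1.51e-06 for macrophages and 2.66e-06 for cell cycle.

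**Figure D1:**
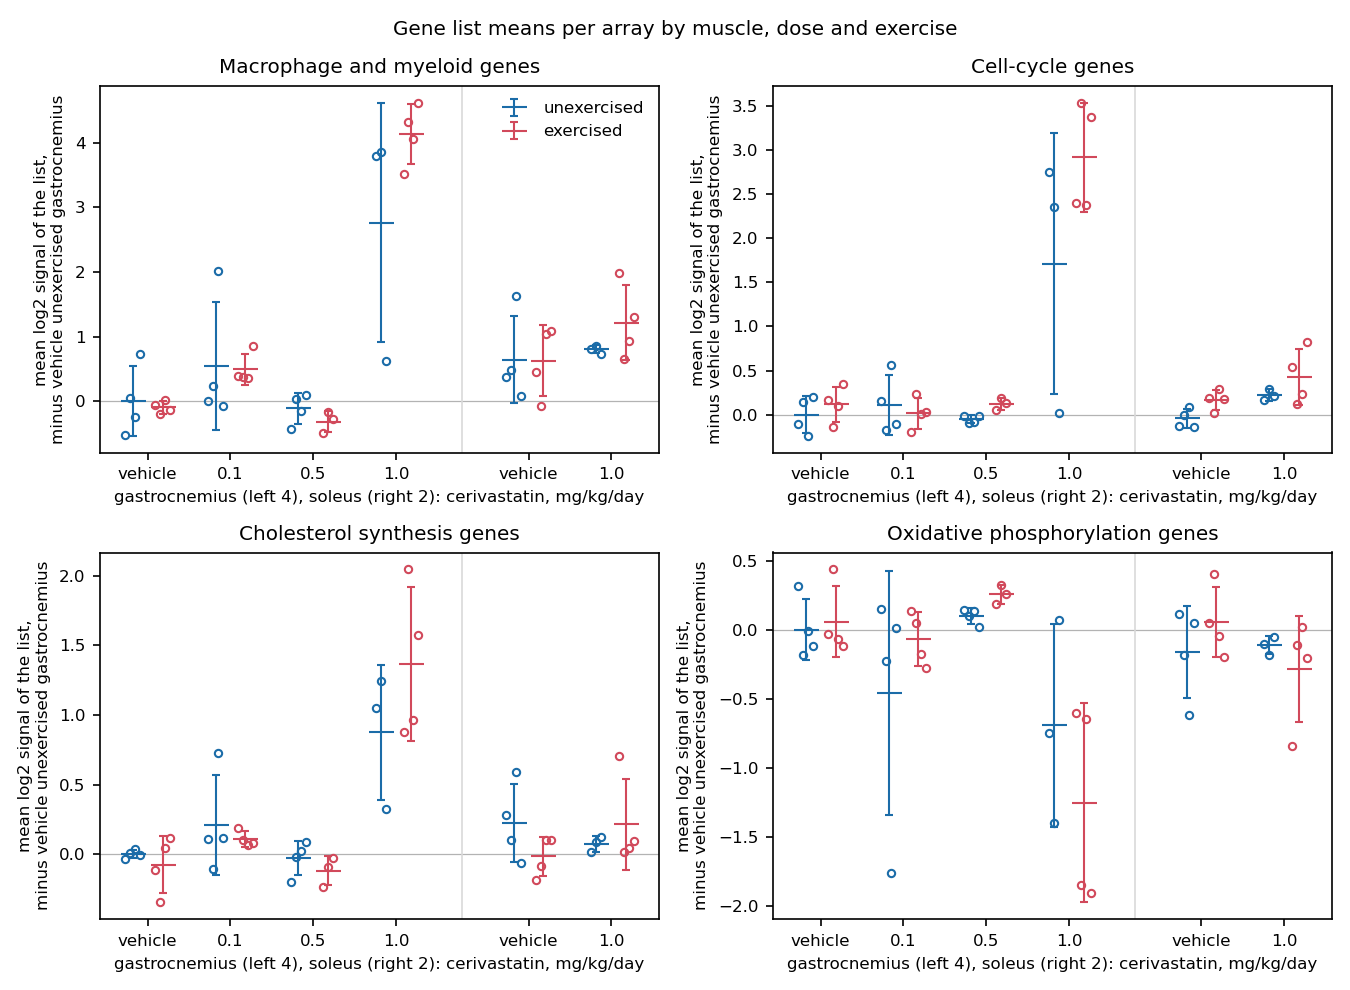
Mean log2 signal of 4 gene lists per array (circles), with the group mean and SD, as the difference from the mean of unexercised vehicle gastrocnemius, against cerivastatin dose in mg/kg/day for 2 muscles. The 4 exercised gastrocnemius arrays at 1.0 mg/kg/day lie above every vehicle array of that muscle for macrophage, cell-cycle and cholesterol genes, and the 3 unexercised ones spread widely (macrophage list mean 11.24 ± 1.85, SD, n = 3).

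Sterol synthesis genes, the pathway that statins inhibit, rose in 15 of 22 measured cases with none lower (15 adjusted over the list alone), with a median of 1.16. Squalene epoxidase (Sqle) rose by 4.69 ± 0.62 (mean signal 1418 against 37.3; limma, BH adjusted p = 9.58e-06), Dhcr7, which catalyses the last step, by 2.88 ± 0.56, and Insig1, a sterol-responsive regulator of the pathway, by 2.80 ± 0.46. Camera gave the list an adjusted p of 5.65e-05, and adjusted p = 0.417 with an estimated correlation. Of 14 fatty acid synthesis genes 5 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.318). Elovl6, Fads1 and Acly rose by 2.70, 2.51 and 2.50. Rhob rose by 1.07 ± 0.32 (limma, BH adjusted p = 0.00871).

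Genes of the contractile and energy machinery fell. In the fast-fibre list 15 of 17 fell (16 adjusted over the list alone; median -1.67), with parvalbumin (Pvalb), a calcium buffer of fast fibres, at -4.33 ± 0.88, the myosin light chain kinase Mylk2 at -4.31 ± 0.69, calsequestrin 1 (Casq1) at -2.93 ± 0.51 and the fast myosin heavy chain Myh4 at -2.04 ± 0.41 (limma, BH adjusted p = 0.000308). In the slow-fibre list 3 of 16 fell (3 adjusted over the list alone; median -0.19, which is 0.07 under quantile normalization). The slow myosin heavy chain Myh7 was at -0.25 ± 1.94 (limma, BH adjusted p = 0.931). Of 69 oxidative phosphorylation genes 66 fell and 2 rose (67 and 2 adjusted over the list alone; median -1.33), with Cox8b at -2.52 ± 0.60 and the complex I gene Ndufs3 at -2.22 ± 0.51. TCA cycle genes fell in 16 of 17 cases (16 adjusted over the list alone), with the isocitrate dehydrogenase gene Idh3a at -2.53 ± 0.55. Glycolysis and glycogen genes fell in 23 of 28 and rose in 3 (24 and 3 adjusted over the list alone), with Gpd1 at -4.33 ± 0.71 and the lactate transporter Slc16a3 at -4.23 ± 0.76. Calcium and excitation-contraction genes fell in 21 of 23 and rose in 1 (21 and 1 adjusted over the list alone), with the junctional membrane genes Jph1, Sypl2 and Stac3 between -3.40 and -3.35. Fatty acid oxidation genes fell in 19 of 33 and rose in 3 (20 and 3 adjusted over the list alone), with the uncoupling proteins moving apart, Ucp3 at -3.27 ± 0.61 and Ucp2 at 2.70 ± 0.41. The treated arrays were not alike in these lists. The median shift of slow-fibre genes from exercised vehicle was 2.43 and 2.00 in replicates 1 and 3 and -3.10 and -1.58 in replicates 2 and 4. In the same order it was -0.703, -0.734, -1.91 and -2.01 for oxidative phosphorylation and -1.48, -1.48, -3.72 and -3.81 for calcium genes. Camera adjusted p ran from 3.71e-14 for oxidative phosphorylation to 0.000446 for fatty acid oxidation over these 6 lists, slow fibres aside (camera adjusted p = 0.286). None held with an estimated correlation (adjusted p = 0.417 with an estimated correlation for fast fibres, glycolysis and calcium, adjusted p = 0.425 for oxidative phosphorylation and TCA cycle, and adjusted p = 0.533 for fatty acid oxidation).

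Stress and degradation genes were mixed. In the unfolded protein list 15 of 26 rose and 3 fell (15 and 3 adjusted over the list alone), led by Edem1, which acts in disposal of misfolded proteins, at 3.44 ± 0.48. In the oxidative stress list 11 of 25 rose and 2 fell (12 and 2 adjusted over the list alone), with heme oxygenase Hmox1 at 4.25 ± 0.57 and the aldo-keto reductase Akr1b8 at 4.09 ± 0.83. Of 24 p53 and apoptosis genes 14 rose and 1 fell (14 and 2 adjusted over the list alone), led by Bcl2a1, Casp6 and Bid. Of 27 immediate early genes 14 rose and 1 fell (14 and 1 adjusted over the list alone), with Myc, Ier3 and Egr1 between 2.78 and 3.10. Lysosome and autophagy genes rose in 19 of 32 and fell in 3 (19 and 4 adjusted over the list alone), with the cathepsin Ctsz at 3.26 ± 0.36 and granulin (Grn) at 3.02 ± 0.40. Among proteasome genes 8 of 32 fell (7 adjusted over the list alone), by less than 1 log2 unit each, and among heat shock genes 2 of 19 rose and 4 fell (2 and 3 adjusted over the list alone). In the atrophy list 3 of 26 rose and 7 fell (3 and 7 adjusted over the list alone), with myostatin (Mstn) at -4.20 ± 0.83 and the metallothionein Mt2A at 3.41 ± 0.59. The muscle ubiquitin ligases Fbxo32 (-0.84 ± 0.52, limma, BH adjusted p = 0.20) and Trim63 (-1.10 ± 0.56, adjusted p = 0.116) did not pass. Camera adjusted p was 0.00299 for both the unfolded protein and p53 lists, 0.00155 for lysosome, 0.00972 for immediate early, 0.0849 for oxidative stress, 0.0898 for proteasome, 0.11 for heat shock and 0.147 for atrophy. With an estimated correlation the first 4 had adjusted p = 0.425, adjusted p = 0.417, adjusted p = 0.417 and adjusted p = 0.496 respectively.

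Lists of regeneration and of other tissue components were called in part. Of 26 myogenic and denervation genes 7 rose and 5 fell (7 and 6 adjusted over the list alone), including Vim at 2.38 ± 0.43 and Ankrd1 at 2.08 ± 0.79 (limma, BH adjusted p = 0.0343), while Myog (0.84 ± 0.48, adjusted p = 0.165) and Cdkn1a (0.84 ± 0.42, adjusted p = 0.112) did not pass. Of 9 satellite cell genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Vcam1 at 3.66 ± 0.47. Of 15 endothelial genes 4 rose (2 adjusted over the list alone), and of 7 mast cell genes 3 rose (0 adjusted over the list alone). Of 16 adipocyte genes 1 rose and 6 fell (1 and 6 adjusted over the list alone), among them Gpd1, Slc2a4 and Plin4, which muscle also expresses. Of 11 smooth muscle genes 1 rose and 3 fell (1 and 2 adjusted over the list alone), and of 8 Schwann cell genes 1 rose (0 adjusted over the list alone). Of 5 erythroid genes 0 passed by limma, also adjusted over the list alone. Ribosomal protein genes rose in 10 of 27 and fell in 1 (9 and 1 adjusted over the list alone), with a median of 0.22 that is -0.05 under median centring. Camera adjusted p for these 9 lists ran from 0.0961 to 0.932.

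In total 9424 of 21729 probe sets (43.4%) changed in exercised rats at this dose, 4990 up and 4434 down, by limma at a BH adjusted p under 0.05. Counted by the 1 probe set that represents each gene, 3240 genes were higher and 2558 lower. Of the probe sets called, 1947 had no single symbol, and 59 symbols had probe sets called in both directions. Centring every array on its median moved the median of all probe sets to -0.28 and gave 3696 higher and 6315 lower.

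**Figure D2:**
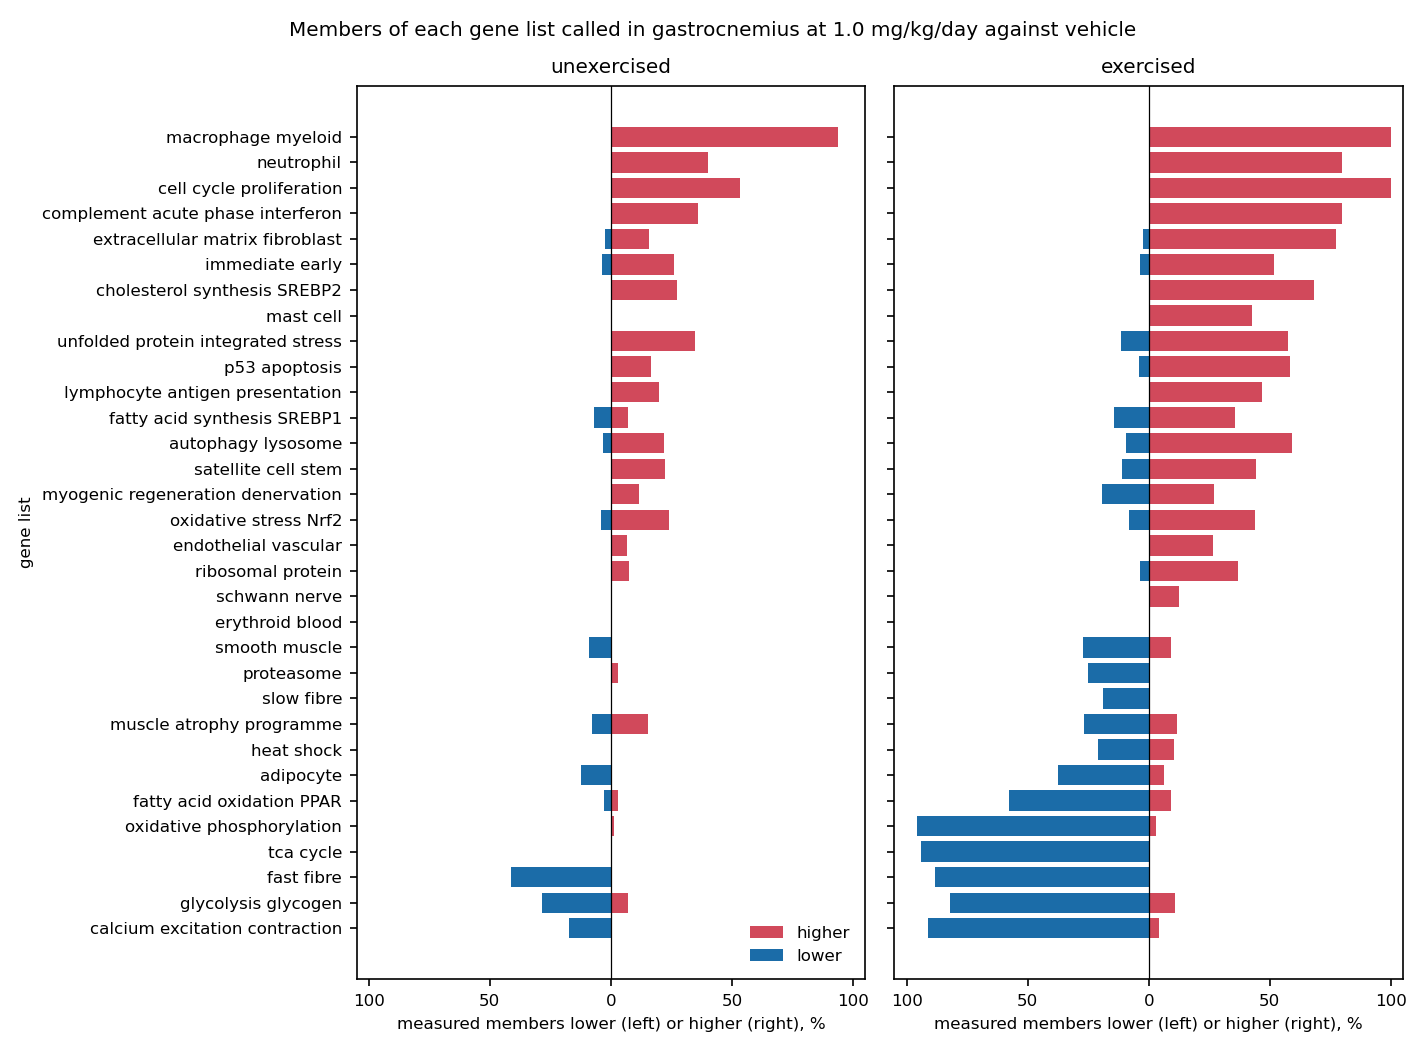
Share of the measured members of each of 32 gene lists called higher (right, red) or lower (left, blue) at 1.0 mg/kg/day against vehicle in unexercised and exercised gastrocnemius, in % (limma, BH adjusted p under 0.05). Macrophage genes are called in 31 of 33 cases without and 33 of 33 with exercise, and oxidative phosphorylation genes are called lower in 0 of 69 without and 66 of 69 with exercise. These counts do not test exercise, whose interaction with this dose called 0 probe sets. The oxidative phosphorylation median was shifted from vehicle by -0.76, -1.40 and 0.068 in unexercised replicates 1, 2 and 3. In the exercised arrays it was shifted by -0.703 to -2.01. Medians of the slow-fibre, smooth muscle, Schwann cell, erythroid and ribosomal protein lists in exercised rats, and of the slow-fibre, atrophy, heat shock and adipocyte lists in unexercised rats, are not of the same sign under every scaling.

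In unexercised gastrocnemius at 1.0 mg/kg/day, 31 of 33 macrophage genes, 17 of 32 cell-cycle genes and 6 of 22 sterol synthesis genes rose, and 7 of 17 fast-fibre and 8 of 28 glycolysis genes fell. These calls rest on 2 of the 3 treated arrays. The median shift from vehicle was 3.59 and 3.71 for macrophage genes and 2.47 and 2.12 for cell-cycle genes in replicates 1 and 2, against 0.522 and 0.071 in replicate 3. Of 75 named gene calls, 74 were lost without replicate 1 and 74 without replicate 2. Spp1 rose by 6.83 ± 0.91 (mean signal 17160, n = 3, against 80.22, n = 4; limma, BH adjusted p = 0.00104), Ccl7 and Ccl2 each by 4.99, and Fcgr2b by 4.56 ± 0.72. Akr1b8, Timp1, S100a9 and the acute phase gene Serpina3n rose by 4.08 to 4.28. Among genes whose arrays did not overlap between the groups, the largest falls were in LOC102552344 (-3.76 ± 0.90), C8h3orf18 (-3.29 ± 0.83), the sodium pump subunit Atp1b2 (-3.23 ± 0.63), the AMP kinase subunit Prkag3 (-2.90 ± 0.85), the transcription factor Hlf, Mylk2, Gucy2g and Fn3k. For each of these 16 genes the 3 treated arrays lay beyond the 4 vehicle arrays. Mss51 (-5.56 ± 1.23) and Pvalb (-4.56 ± 0.95) fell by more, but their arrays overlapped.

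Macrophage genes rose in 31 of 33 cases in unexercised rats (33 adjusted over the list alone; median 2.60). Of the cell-cycle genes 17 of 32 rose (25 adjusted over the list alone), with Mki67 at 3.76 ± 0.88. Of the sterol synthesis genes 6 of 22 rose (8 adjusted over the list alone), with Sqle at 2.60 ± 0.67, Idi1 at 2.04 ± 0.42 and Insig1 at 2.01 ± 0.49. Unfolded protein genes rose in 9 of 26 (15 higher and 1 lower adjusted over the list alone), with Edem1 at 2.56 ± 0.52 and asparagine synthetase (Asns) at 2.45 ± 0.56. Immediate early genes rose in 7 of 27 and fell in 1 (13 and 1 adjusted over the list alone), with Myc at 2.69 ± 0.61 and Fos at 2.52 ± 0.82. Rhob was at 0.44 ± 0.35 (limma, BH adjusted p = 0.434). Matrix genes rose in 7 of 44 and fell in 1 (17 and 1 adjusted over the list alone). Fast-fibre genes fell in 7 of 17 (15 adjusted over the list alone), with Myh4 at -2.17 ± 0.44. Glycolysis genes fell in 8 of 28 and rose in 2 (19 and 2 adjusted over the list alone). Calcium handling genes fell in 4 of 23 (7 lower and 1 higher adjusted over the list alone), with the calcium channel gene Cacna1s at -2.12 ± 0.68. Among oxidative phosphorylation genes 1 of 69 rose and none fell (0 adjusted over the list alone), and their median was -0.71. Ankrd1 rose by 3.40 ± 0.85 and Cdkn1a by 1.46 ± 0.46 (limma, BH adjusted p = 0.0441). Vehicle replicate 1 was low in Cdkn1a, with a log2 signal of 9.56 against 10.78 to 10.94 in the other vehicle arrays. Myog (1.46 ± 0.52, adjusted p = 0.0712), Trim63 (0.82 ± 0.61, adjusted p = 0.397), Fbxo32 (0.22 ± 0.56, adjusted p = 0.837) and Myh7 (-0.19 ± 2.10, adjusted p = 0.964) did not pass. Camera adjusted p was 3.06e-21 for macrophage, 3.12e-11 for cell cycle, 0.000198 for sterol and 2.17e-10 for oxidative phosphorylation genes, the last with a fry adjusted p of 0.132. None of the 33 lists held with an estimated correlation (adjusted p = 0.397 or above with an estimated correlation).

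In total 2065 probe sets (9.5%) passed in unexercised rats, 1238 higher and 827 lower (limma, BH adjusted p under 0.05). Median centring, which moved the median of all probe sets to -0.13, gave 987 higher and 1133 lower. The group was not uniform: along the direction of the exercised high-dose effect its 3 arrays lay at 0.783, 0.861 and 0.100 of that effect. By limma 5823 probe sets passed without the third, against 5 without the first and 2 without the second. Leaving out vehicle replicates 1, 2 or 3 gave 823, 741 and 733, and a fit on only these 7 arrays called 0. In the fit on all groups, 4113 passed without the 3 arrays of lowest 5' to 3' ratio, an alternative chosen after seeing the data. None of these arrays is in the groups compared here, so the fold changes stayed the same and only the estimate of the spread differed.

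**Figure D3:**
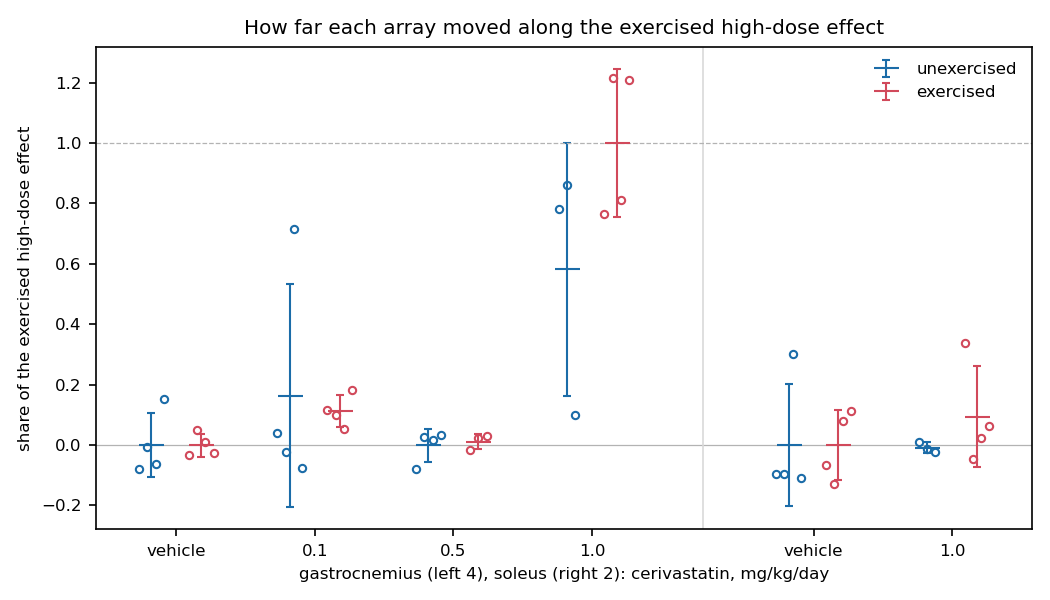
Position of every array (circles) along the exercised high-dose effect, as a share of that effect over 5798 genes, with group mean and SD, against dose in mg/kg/day for 2 muscles. The exercised high-dose arrays average 1 by construction. Unexercised high-dose gastrocnemius arrays lie at 0.783, 0.861 and 0.100, and 1 array at 0.1 mg/kg/day lies at 0.714.

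At the lower doses no gene passed in either exercise state. By limma at a BH adjusted p under 0.05, 0 of 21729 probe sets changed at 0.1 mg/kg/day and 0 at 0.5 mg/kg/day without exercise, with 885 and 593 (4.07% and 2.73%) at an unadjusted p under 0.05. With exercise the counts were 0 and 0, with 957 and 626 (4.4% and 2.88%) at an unadjusted p under 0.05. Chance alone gives on average 1 in 20 probe sets at an unadjusted p under 0.05, so these counts are no sign of an effect. Insig1 was at 0.57 ± 0.46 and -0.09 ± 0.46 without exercise and at 0.24 ± 0.46 and 0.06 ± 0.49 with it. The macrophage list mean was 9.01 ± 0.99 (SD, n = 4) at 0.1 and 8.36 ± 0.23 at 0.5 mg/kg/day without exercise, against 8.47 ± 0.54 in vehicle and 11.24 ± 1.85 (n = 3) at 1.0 mg/kg/day. With exercise it was 8.96 ± 0.24 (n = 4) at 0.1 and 8.15 ± 0.17 (n = 3) at 0.5 mg/kg/day, against 8.37 ± 0.10 in vehicle. At 0.1 mg/kg/day with exercise its median change was 0.57 (camera adjusted p = 9.2e-06, adjusted p = 0.949 with an estimated correlation; 0 of 33 past the threshold by limma, also adjusted over the list alone). The 4 arrays of that group lay at 0.054 to 0.183 of the exercised high-dose effect, against -0.033 to 0.05 in exercised vehicle, whose arrays also define that effect. At 0.5 mg/kg/day with exercise the arrays lay at -0.017 to 0.03. The mean log2 5' to 3' ratio was -1.08 ± 0.126 (SD) at 0.1 mg/kg/day with exercise, against -0.741 ± 0.101 in exercised vehicle. In the unexercised 0.1 mg/kg/day group, replicate 3 had the lowest 5' to 3' ratio of all arrays and lay at 0.714 of the exercised high-dose effect, where the other 3 lay between -0.076 and 0.041. Camera called 16 of the 33 lists in that comparison and 10 at 0.1 mg/kg/day with exercise, and 1 and 7 at 0.5 mg/kg/day without and with it. None held with an estimated correlation (in this order, lowest adjusted p = 0.526, adjusted p = 0.949, adjusted p = 0.994 and adjusted p = 0.969).

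The trend over dose followed the high dose. In exercised rats 9819 probe sets had a dose trend by limma (5144 rising, 4675 falling; 3873 and 6359 with median centring). In unexercised rats 1508 had one (871 rising, 637 falling; 712 and 813 with median centring). The unexercised count was 0 without high-dose replicate 1 or replicate 2 and 5335 without replicate 3. It was 4910 without replicate 3 at 0.1 mg/kg/day, 665 and 682 without replicates 4 and 2 of that dose, and 854, 690 and 752 without vehicle replicates 1, 2 and 3. It was 551 on dose rank, and 0 in the fit on unexercised gastrocnemius arrays only.

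Exercise by itself changed no gene past the threshold in vehicle gastrocnemius. The number of probe sets was 0 by limma, with 724 (3.33%) at an unadjusted p under 0.05, and Ankrd1 (1.54 ± 0.79) and Cdkn1a (0.79 ± 0.42) each had a BH adjusted p of 1. The Cdkn1a difference rests in part on unexercised vehicle replicate 1, with a log2 signal of 9.56 against 10.78 to 10.94 in the rest of its group. Slow-fibre genes had a median of -2.11 (0 of 16 past the threshold by limma, also adjusted over the list alone; camera adjusted p = 3.33e-05, adjusted p = 1 with an estimated correlation), and Myh7 was at -3.32 ± 1.94. Myh7 varied over the arrays of both groups.

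Exercise combined with the drug was tested as an interaction. For 1.0 mg/kg/day no probe set passed (0 by limma, with 1375, or 6.33%, at an unadjusted p under 0.05), and the median SE of an interaction was 0.508. The effect of the drug on Insig1 was 0.79 ± 0.67 larger with exercise (interval -0.56 to 2.15; limma, BH adjusted p = 0.728) and that on Trim63 differed by -1.92 ± 0.83 (adjusted p = 0.705). Interaction medians were 1.53 for macrophage genes (camera adjusted p = 1.67e-11), 0.99 for cell-cycle genes (camera adjusted p = 8.11e-08) and -1.13 for calcium handling genes (camera adjusted p = 2e-06), with 0 members of each past the threshold by limma. With an estimated correlation each had adjusted p = 0.615. These medians rest largely on unexercised high-dose replicate 3. Without it they were 0.35 (camera adjusted p = 0.00654), 0.18 (camera adjusted p = 0.148) and -0.53 (camera adjusted p = 0.00774), and 0 probe sets passed by limma. The calcium median was -0.74 without exercised high-dose replicate 2. The interactions at 0.1 and 0.5 mg/kg/day also gave 0 by limma, with 609 and 590 (2.8% and 2.72%) at an unadjusted p under 0.05. Across 11684 genes, the high-dose changes with and without exercise, measured on separate arrays, correlated at r = 0.882 (Spearman 0.851; genes are not independent replicates). Both comparisons called 817 genes higher and 434 lower, with 0 in opposite directions, where independent lists would share 237.1 and 101.4.

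**Figure D4:**
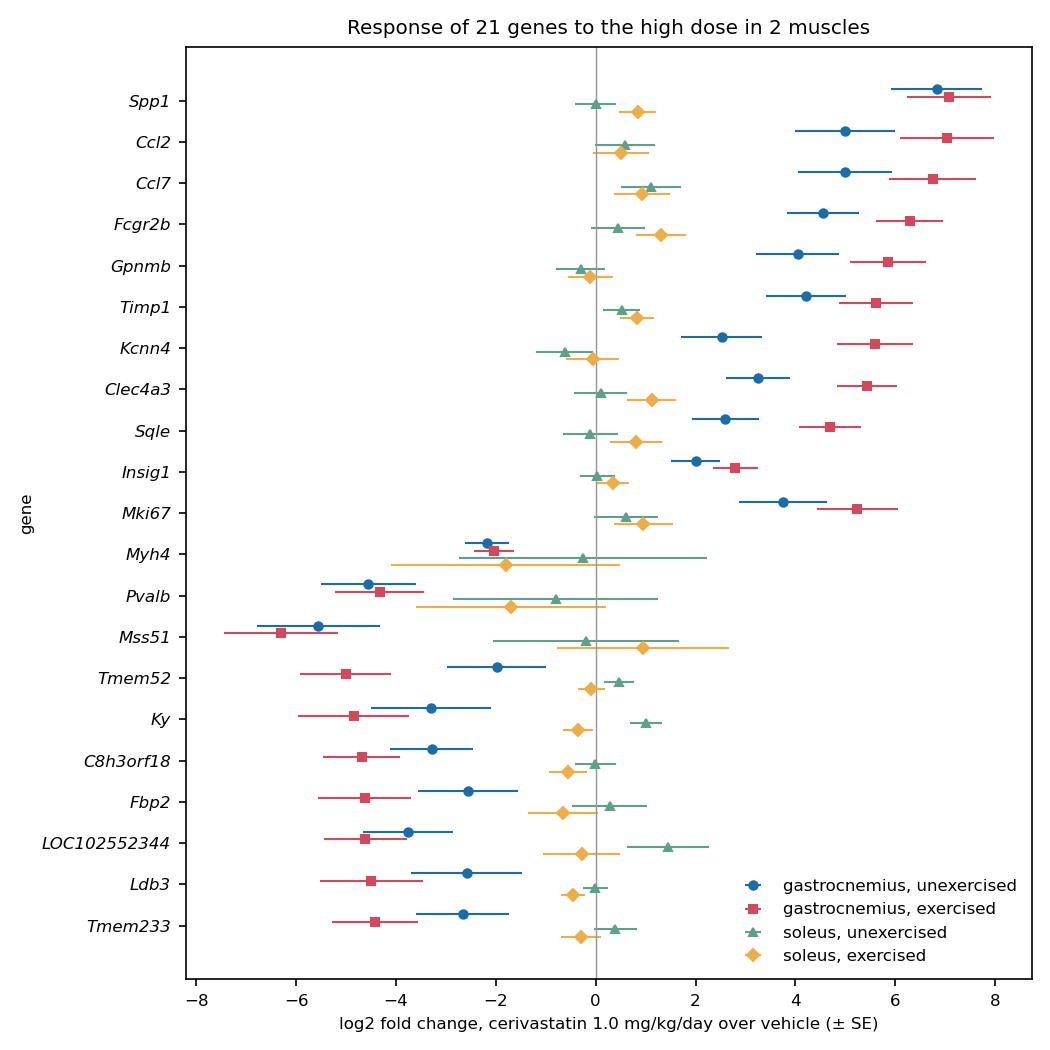
Log2 fold change (± SE, from limma) at 1.0 mg/kg/day over vehicle of 21 genes in 4 comparisons: gastrocnemius and soleus, each without and with exercise. Spp1 is at 6.83 and 7.08 in gastrocnemius and at 0.84 in exercised soleus, and Mss51 is at -6.31 in exercised gastrocnemius.

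In the soleus no gene changed past the threshold at 1.0 mg/kg/day. By limma 0 probe sets passed without exercise (593, or 2.73%, at an unadjusted p under 0.05) and 0 with exercise (1156, or 5.32%, at an unadjusted p under 0.05). Insig1 was at 0.03 ± 0.35 without exercise and 0.34 ± 0.32 with it, and Spp1 in exercised soleus was at 0.84 ± 0.37 (limma, BH adjusted p = 0.908). Each Insig1 value includes 1 outlying array, so their order is uncertain. Unexercised vehicle replicate 3 had a log2 signal of 10.76, against 9.56 to 9.73 in the rest of its group. Exercised high-dose replicate 1 had 11.09, against 9.53 to 9.71. In exercised soleus the macrophage list had a median of 0.55 (camera adjusted p = 9.59e-09) and the oxidative phosphorylation list -0.34 (camera adjusted p = 1.3e-18), with 0 members of either past the threshold by limma, also adjusted over the list alone. With an estimated correlation these had adjusted p = 0.669 and adjusted p = 0.667. Camera called 16 lists there, and 0 with an estimated correlation (lowest adjusted p = 0.667). Of the 16, 10 were lost without treated replicate 1 (3 of them turned in direction), 6 without vehicle replicate 2, and 9 without the 3 arrays of lowest 5' to 3' ratio (4 turned), an alternative chosen after seeing the data. Of the 4 treated arrays, 1 (replicate 1) lay at 0.337 of the gastrocnemius effect and the others between -0.045 and 0.062. This array, also 1 of those 3, had a Cfd signal of 41070 and an Mbp signal of 15190 (adipocyte and myelin genes), against at most 8481 and 513 in the other treated arrays. Without it the macrophage median was 0.35 and that of oxidative phosphorylation -0.15. In unexercised soleus the immediate early list had a median of 0.47 and the atrophy list 0.46 (camera adjusted p = 2.27e-06 and 2.38e-05), with adjusted p = 0.377 with an estimated correlation for both. Exercise in vehicle soleus and the interaction of exercise with the drug gave 0 by limma (645 and 705, or 2.97% and 3.24%, at an unadjusted p under 0.05). Camera called 11 and 19 lists for them, none with an estimated correlation (lowest adjusted p = 0.357 and adjusted p = 0.727).

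The difference between the muscles was tested directly. In exercised rats the high-dose effect differed between soleus and gastrocnemius for 5491 probe sets, 2523 more positive and 2968 more negative in soleus (limma, BH adjusted p under 0.05). Median centring, which moved the median of all probe sets to 0.22, gave 3444 and 2187. The effect in soleus minus that in gastrocnemius was -6.54 ± 1.21 for Ccl2, -6.24 ± 1.05 for Spp1, -5.96 ± 1.00 for Gpnmb and -5.82 ± 1.14 for Ccl7. Kcnn4, Kifc1, Lilrb4 and Myo1f lay between -5.66 and -5.17. Sqle differed by -3.89 ± 0.85 and Insig1 by -2.46 ± 0.61 (limma, BH adjusted p = 0.00367). In the other direction stood Mss51 (7.26 ± 2.06), Tmem52 (4.92 ± 1.11), Plcd4 (4.67 ± 1.10), LOC100910189, Ky, Gpd1 (4.36 ± 1.05), LOC102552344 and Mylk2 (4.23 ± 0.85). Of these, at least Mss51 (-5.82), LOC102552344 (-5.00) and Gpd1 (-2.61) were already lower in soleus than in gastrocnemius of unexercised vehicle rats. A low starting level can leave less room to fall, which this test does not separate from a weaker drug effect. Of the macrophage genes 32 of 33 differed (33 adjusted over the list alone), of the cell-cycle genes 28 of 32 (31 adjusted over the list alone) and of the sterol genes 10 of 22 (12 lower and 1 higher adjusted over the list alone). All of those past the threshold over all genes were more negative in soleus. Calcium handling genes were more positive in soleus in 19 of 23 (20 and 1 more negative adjusted over the list alone), glycolysis genes in 20 of 28 with 3 more negative (23 and 3 adjusted over the list alone), and oxidative phosphorylation genes in 14 of 69 with 2 more negative (21 and 2 adjusted over the list alone). In exercised vehicle rats the calcium list mean was 12.36 in soleus and 13.06 in gastrocnemius. Means there were 12.41 and 13.57 for glycolysis and 14.26 in both muscles for oxidative phosphorylation. No camera call here held with an estimated correlation (adjusted p = 0.416 or above with an estimated correlation). Pvalb (2.64 ± 2.01, adjusted p = 0.356) and Myh4 (0.23 ± 2.13, adjusted p = 0.955; -0.41 under quantile normalization) did not differ past the threshold. In unexercised vehicle soleus the Pvalb signal was 181.5, 24000.5, 4126 and 297 in the 4 arrays.

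In unexercised rats the same test called 2 probe sets, Spp1 (-6.83 ± 1.13, limma, BH adjusted p = 0.0113) and Prr12 (1.72 ± 0.32, adjusted p = 0.0378), with 3929 (18.1%) at an unadjusted p under 0.05. Without replicate 3 of the unexercised high-dose gastrocnemius 3558 passed. By limma 0 passed without its replicate 1 or replicate 2 or without replicate 3 of vehicle soleus, 1 without vehicle gastrocnemius replicate 4, high-dose soleus replicate 2 or vehicle soleus replicates 1 or 2, and 5 without high-dose soleus replicate 3.

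Vehicle soleus and gastrocnemius of unexercised rats differed in 1526 probe sets, 709 higher and 817 lower in soleus (limma, BH adjusted p under 0.05; 483 and 951 with median centring). Higher in soleus were albumin (Alb) by 4.71 ± 1.31, the embryonic myosin Myh3 by 4.13 ± 0.89, sarcolipin (Sln), a regulator of the calcium pump, by 3.96 ± 1.03, and Iah1, Fhl2, haptoglobin (Hp), Slc4a3 and Spp1 by 3.37 to 3.51. Lower in soleus were Mss51 (-5.82 ± 1.46), Pvalb (-5.26 ± 1.42), Myh4 (-5.07 ± 1.51), LOC102552344 (-5.00 ± 0.79), the fast myosin binding protein Mybpc2 (-4.96 ± 1.13), the fast-fibre actinin Actn3 (-4.78 ± 1.33), Cd24 (-4.51 ± 0.79) and Gpt2 (-4.07 ± 0.87). For these 16 genes the 4 soleus arrays lay beyond the 4 gastrocnemius arrays. Fast-fibre genes were lower in 10 of 17 cases (11 adjusted over the list alone; camera adjusted p = 4.23e-09, adjusted p = 0.77 with an estimated correlation; fry adjusted p = 0.018). Glycolysis genes were lower in 11 of 28 (17 lower and 2 higher adjusted over the list alone), with Fbp2 at -3.54 ± 0.90. Of 16 slow-fibre genes 1 passed, the cardiac and slow calsequestrin Casq2 at 2.91 ± 0.61 (1 adjusted over the list alone), and Myh7 was at 0.61 ± 1.63 (limma, BH adjusted p = 0.861). The slow-fibre list mean was 14.84 ± 0.23 (SD, n = 4) in soleus and 13.7 ± 0.69 (n = 4) in gastrocnemius. The SE rests on all 45 arrays, and the list's SD reached 2.32 in another gastrocnemius group (0.1 mg/kg/day, unexercised). So few calls do not show that the muscles are alike in these genes. Of 16 adipocyte genes 2 were higher and 2 lower in soleus (6 and 2 adjusted over the list alone), with Aqp7 at 2.95 ± 0.79 and Cidea at 2.64 ± 0.59. Myod1, a myogenic factor, was at -2.62 ± 0.54. The count was 745 without gastrocnemius replicate 3, 808 without its replicate 2, and 747 and 857 without soleus replicates 1 and 4. Soleus replicate 3, 1 of the 3 arrays of lowest 5' to 3' ratio, had a signal of 40880 for the adipocyte gene Cfd and 13190 for the myelin gene Mbp, against at most 6545 and 422.5 in the other soleus arrays. Without it Alb (3.86, adjusted p = 0.101) and Hp (3.09, adjusted p = 0.0829) did not pass, while Aqp7 (2.98, adjusted p = 0.0367) and Cidea (2.60, adjusted p = 0.0148) did. Of the 9 lists that camera called, 4 were lost without this array (atrophy, proteasome, macrophage and unfolded protein), and none held with an estimated correlation (adjusted p = 0.77 for each). Of 53 named gene calls, 13 were lost without it and 31 without soleus replicate 1. Input RNA differed between the muscles as described.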

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

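Of the tests in the weighing below, those of the cell-cycle genes and the 4 lists beside them, of fat, nerve and vessel tissue in the low-dose sample, of the marker medians in the 3 arrays, and of both relations outside the high-dose gastrocnemius groups were chosen only after the result was seen.

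Of 106 tests of whether the highest or lowest array of a group of 4 stood far from the rest, 14 were positive, and chance gives about 1 in 20. Each value is the gap to the nearest other array as a share of the group's range. In unexercised gastrocnemius at 0.1 mg/kg/day, replicate 3 stood apart in Fbxo32 (0.872; log2 signal 6.25 against 8.50 to 8.83), Trim63 (0.859; 9.37 against 12.18 to 12.64), the mean log2 5' to 3' ratio (0.868; -2.09 against -0.89 to -0.70) and the share of the exercised high-dose effect (0.852; 0.714 against -0.076 to 0.041), and replicate 4 in Ankrd1 (0.879; 7.96 against 9.49 to 9.70). Unexercised vehicle soleus replicate 3 stood apart in Insig1 (0.858; 10.76 against 9.56 to 9.73), Rhob (0.840; 12.91 against 12.54 to 12.60) and the share of the exercised effect (0.973; 0.303 against -0.108 to -0.097). Exercised high-dose soleus replicate 1 stood apart in Insig1 (0.887; 11.09 against 9.53 to 9.71). Exercised vehicle soleus replicate 1 was low in Rhob (0.922; 12.39 against 12.75 to 12.79). Unexercised vehicle gastrocnemius replicate 1 was low in Cdkn1a (0.885; 9.56 against 10.78 to 10.94) and its replicate 4 in Fbxo32 (0.887; 8.49 against 9.10 to 9.18). Exercised gastrocnemius at 0.1 mg/kg/day had a low Cdkn1a in replicate 4 (0.872; 10.42 against 10.82 to 10.88). Unexercised gastrocnemius at 0.5 mg/kg/day had a low share of the exercised effect in replicate 1 (0.858; -0.081 against 0.016 to 0.032).

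The effect of the high dose differed between the muscles in 5491 probe sets with exercise and in 2 without, by limma's interaction term with BH adjustment. Without unexercised high-dose gastrocnemius replicate 3 the second count was 3558, and whether the muscles differ more with exercise than without was not tested. The report gives the genes.

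In unexercised gastrocnemius, 1 high-dose array (replicate 3) lay at 0.100 of the exercised high-dose effect and 1 low-dose array (replicate 3 at 0.1 mg/kg/day) at 0.714. Of 5 lists, an exchange of their labels was argued against by the cell-cycle genes alone, whose median was shifted by 0.463 in the low-dose array where the 2 responding high-dose arrays had 2.47 and 2.12 and the exercised ones at least 2.01. The 4 others came closer to the responding arrays or reached them, with medians of 2.10 for macrophage (3.59 and 3.71 in those arrays), 0.98 for sterol synthesis (0.69 and 1.12), -1.51 for fast-fibre (-1.04 and -2.14) and -1.84 for oxidative phosphorylation genes (-0.76 and -1.40), but vehicle soleus replicate 3, which had no drug, was also shifted from its group in 3 of them (1.40, 0.545, -0.039 and -0.637 in this order). Low RNA integrity of the low-dose array stays open, because on 394 genes that the other 2 arrays of low 5' to 3' ratio do not move it lay at 0.431 of the effect (0.827 and 0.892 in the responding arrays), between the bounds set for this explanation and for an exchange. Fat, nerve and vessel tissue in that sample may also account for its shift: the adipocyte, Schwann cell, smooth muscle and endothelial lists were all higher in it than in its group, the lowest of their medians by 2.30, which leaves the high-dose array without the response unexplained, and a weaker response of that animal stays open as untested.

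The 3 arrays of lowest 5' to 3' ratio (that low-dose gastrocnemius, exercised high-dose soleus replicate 1 and unexercised vehicle soleus replicate 3) deviated from their groups alike (r = 0.714 to 0.734 across genes), and the design gives no biological explanation that was tested. RNA integrity stays open: over the 42 other arrays the deviation along this direction went with the 5' to 3' ratio at r = -0.315 (permutation p = 0.131; rho = -0.255, permutation p = 0.185; r = -0.189 without the 2 farthest; BH adjusted p = 0.218), and over the 35 outside the high-dose gastrocnemius groups at r = -0.567 (permutation p = 0.0475; rho = -0.396, permutation p = 0.0863; r = -0.425 without the 2 farthest; BH adjusted p = 0.119, over 5 relations). Fat and nerve tissue in the samples is a candidate explanation, as the 6 medians of the adipocyte (16 genes, 7 of them above log2 10 in vehicle gastrocnemius and 3 in another list) and Schwann cell lists (8 genes, 1 and 0) were at least 1.73 higher in these arrays, with Mbp signals of 19240, 15190 and 13190 where the rest of their groups lay at most at 2350, 513 and 422.5, and Cfd of 43970, 41070 and 40880 against at most 2154, 8481 and 6545, while Car3, an adipocyte list gene at a high level in these muscles, was lower than in the rest (48870, 47400 and 56160 against at least 63540, 62100 and 58980). The score of these lists went with the direction at r = 0.044 over the 42 other arrays (permutation p = 0.893; rho = 0.264, permutation p = 0.189; r = 0.305 without the 2 farthest; BH adjusted p = 0.929), and at r = 0.807 over the 35 outside the high-dose gastrocnemius groups (permutation p = 1e-05, the smallest that 100000 resamples give; rho = 0.77, permutation p = 6e-05; r = 0.823 without the 2 farthest; BH adjusted p = 5e-05). Over the 42 arrays the relation fell on the side set beforehand as against this explanation. The high-dose gastrocnemius groups were left out only after that was seen, because their arrays differ in the drug response. In 1 of these groups the shares of the exercised high-dose effect were 0.783, 0.861 and 0.100. Whether these arrays also vary along the shared direction was not tested, so the relation over 35 arrays cannot decide for this explanation.

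Slow-fibre genes varied between arrays within gastrocnemius groups, with Myh7 signals from 11.5 to 85000, and the design gives no biological explanation that was tested. RNA integrity was argued against, as the slow-fibre score and the 5' to 3' ratio had r = -0.019 over 30 arrays (permutation p = 0.929; rho = -0.01, permutation p = 0.963; r = -0.181 without the 2 farthest; BH adjusted p = 0.929). A varying share of slow-fibre tissue in the piece sampled is a candidate explanation, since within groups the 15 other slow-fibre genes had a median r of 0.878 with Myh7 (12 above 0.5; range -0.219 to 0.985), against 0.038 for 17 fast-fibre genes.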

How the results depend on the processing

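The alternatives that leave out the 3 arrays of lowest 5' to 3' ratio or add the slow-fibre score were chosen only after the data were seen. Leaving out 1 array gave 7625 to 9447 probe sets for the high dose in exercised gastrocnemius, and each such fit shared at least 7576 of the 9424 with their direction and called 0 the other way. The same high dose without exercise ranged from 2 to 5823, soleus against gastrocnemius from 745 to 1320, the muscle interaction from 3834 to 6248 with exercise and from 0 to 3558 without, and the dose trend from 0 to 5335 without exercise and 7886 to 9723 with it. Counts of 0 became 0 to 1 for 0.1 and 0.5 mg/kg/day, with and without exercise, and for the exercise interaction at 0.1 mg/kg/day, and stayed at 0 in the other comparisons that began there.

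Plain log2 gave 1 call for 0.1 and 2 for 0.5 mg/kg/day with exercise, the offset of 45.3 gave 1 for 0.5, and a prior without trend gave 1 and 3. The unexercised muscle interaction called 1 under quantile normalization, 1 under median centring, 1 without a filter, 8 with the 50th percentile filter and 0 in the fit on only the groups compared. That fit also called 0 for the unexercised high dose and for the unexercised dose trend, and 1 for 0.1 mg/kg/day with exercise. Dose rank gave 551 for the unexercised dose trend. Without the 3 arrays the unexercised high dose called 4113, including all 2065. None of them is in the groups that it compares, so its fold changes stayed the same and only the estimate of the spread differed. The unexercised dose trend called 4910 without them. The unexercised muscle interaction then called 16, 0.1 and 0.5 mg/kg/day with exercise 1 and 2, and the exercise interaction at 0.1 mg/kg/day 1. The cause of the other changes in count was not tested. Fewer arrays estimate the spread in the fit on only the groups compared. The same fit called 9398 for the exercised high dose and 1677 for soleus against gastrocnemius. These counts cannot decide whether fewer arrays account for the 0 in the unexercised high dose. Its treated arrays lay at 0.783, 0.861 and 0.100 of the exercised effect. In the fit on all groups, the unexercised high dose shares its spread with the other groups. Its macrophage list mean had an SD of 1.85 (n = 3), against 0.54 (n = 4) in unexercised vehicle.

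The replicate numbers showed no clear pairing: in 0 of 11 comparisons did every same-numbered pair correlate above 0.1 (r from -0.293 to 0.342), and 15 of 41 arrays matched their own number best. All but soleus against gastrocnemius compare animals of different treatment, where equal numbers cannot mean the same animal. In that comparison r ran from -0.145 to 0.125. Whether both muscles came from the same animals cannot be told from this, and the fits treat their arrays as independent. With the replicate block 2 probe sets passed for 0.5 mg/kg/day with exercise and 1 for the exercise interaction at that dose. The unexercised high dose then called 1541 and the exercised 9369.

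In exercised soleus the ribosomal protein median of -0.11 became 0.068 under quantile normalization. Without the 3 arrays, or without high-dose replicate 1 alone, the proteasome median there was -0.007 with camera's direction turned, fatty acid oxidation was at 0.015 and calcium handling at 0.068, and heat shock was at 0.014 without the 3 arrays. Leaving out any 1 array gave ranges of -0.161 to -0.007, -0.289 to 0.015 and -0.297 to 0.068 for the first 3 of these lists. Of the 107 named gene calls for the exercised high dose, at most 12 were lost under any alternative. Of the 75 for the unexercised one, 75 were lost in the fit on only the groups compared and 74 without replicate 1 or 2. No named gene call changed direction in any comparison. Genes whose signal lies near background limit the size of a measured fold change through the offset.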

Other observations

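All tests of other groupings here were planned, and the comparison of the muscle difference with the drug effect and the look at which arrays the groupings kept apart were chosen only after the results were seen.

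Many genes that separated the muscles in vehicle rats also moved with the drug in exercised gastrocnemius. Of the genes higher in soleus than in gastrocnemius of unexercised vehicle rats, 182 rose at 1.0 mg/kg/day in exercised gastrocnemius, and of those lower in soleus 341 fell, where independent lists would share 124.2 and 116.3, and 50 went opposite ways. These comparisons use separate arrays, and across 11684 genes their changes had r = 0.455 (genes are not independent replicates). Examples are Mss51 (-5.82 and -6.31), Fbp2 (-3.54 and -4.63), Pvalb (-5.26 and -4.33), Gpd1 (-2.61 and -4.33) and Spp1 (3.37 and 7.08). Vehicle soleus replicate 3 itself lay at 0.303 of the exercised high-dose effect, against -0.108 to -0.097 in the rest of its group. The overlap and r were not computed without it. Without this array the muscle differences of these 5 genes were -6.45, -3.68, -5.73, -3.12 and 3.03 in the same order.

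Further lists separated the response of the muscles in exercised rats. Of 26 unfolded protein genes 10 were more negative in soleus and 1, Chac1 (3.14 ± 0.87), more positive (11 and 2 adjusted over the list alone), with Edem1 at -3.39 ± 0.65. Of 25 oxidative stress genes 11 were more negative and 2 more positive (11 and 2 adjusted over the list alone), with Hmox1 at -3.68 ± 0.71. Of 32 lysosome genes 16 were more negative and 3 more positive (19 and 3 adjusted over the list alone), with Ctsz at -2.86 ± 0.47. Camera adjusted p was 0.000782, 0.0227 and 0.000811 for these 3 lists, and each had adjusted p = 0.416 with an estimated correlation. Across genes, the changes in exercised soleus had r = 0.343 with those in exercised gastrocnemius, and those in unexercised soleus r = -0.046.

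Other groupings of the same arrays were counted. For the high dose in exercised gastrocnemius 1 of 35 groupings, the real one, gave as many as 9424 probe sets, and the highest other gave 1. A rank of 1 of 35 is the lowest that these groupings can give, so it makes chance unlikely but does not exclude it. The same holds for soleus against gastrocnemius (1 of 35; 1526 against 1). For the exercised dose trend 1 of 100 gave as many as 9819, but the highest other gave 6654. Large counts thus also arose without the real order of doses, and this rank is not taken to exclude chance. For the exercised muscle interaction 3 of 100 gave as many as 5491, and the highest other gave 8590. All 5 groupings that called more than 1 probe set kept the treated and vehicle gastrocnemius arrays apart (2 as they were, the real one included, and 3 mirrored), whatever the arrangement of the soleus arrays. This count follows the gastrocnemius effect, and its rank is not taken to exclude chance in the difference between the muscles. For the unexercised high dose 1 of 35 gave as many as 2065, but the highest other, with vehicle replicate 4 in place of high-dose replicate 3, gave 2030, and the 5 highest all put high-dose replicates 1 and 2 together. In the unexercised dose trend 2 of 100 gave as many (1508, highest other 4847), and a grouping that calls several times the real count points to a structure of the samples. Since the fit on only the groups compared called 0 for both of these comparisons, and few or none passed without high-dose replicate 1 or 2, these ranks are not taken to exclude chance. For the unexercised muscle interaction chance cannot be excluded (8 of 100; 2 against 694).

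For comparisons with 0 calls by limma, every grouping gives at least as many by construction (35 of 35 or, for interactions, 100 of 100), so that these counts decide nothing about chance. The counts at an unadjusted p under 0.05 are in the report. The highest other grouping gave 30 and 1 for 0.1 and 0.5 mg/kg/day without exercise, 2 and 1 with exercise, and 1 for exercise in vehicle gastrocnemius. In soleus it gave 0 and 1 for the high dose without and with exercise and 2 for exercise in vehicle animals. For the exercise interactions in gastrocnemius it gave 1, 1 and 217 in order of dose, and for that in soleus 1687, which again points to a structure of the samples.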
